A study of Mus musculus with 8 samples.

How the data were processed

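The data are RNA sequencing libraries of cultured cardiomyocytes from C57/Bl6 mouse embryos at day 12.5, 4 grown in control medium and 4 with 10 µM simvastatin, grouped by the treatment label of each sample. RNA was extracted with a column kit for small samples and pooled from male and female embryos, per the labels. The time in simvastatin, the strand setting of the counting, the annotation release and the kind of library are not given in the sources used here. The deposited values are raw counts per gene: per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.5.2b and featureCounts, with Subread 1.5.2, on the builds GRCm38 and mm10. The file headers have the layout of featureCounts, with Ensembl gene identifiers, positions and lengths, and each count column's header names a set, which gave 2 sets of 4 libraries.

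Each table held 49315 genes and no row without a gene name. Symbols came from the GENCODE annotation of the same build, which matched 99.3% of identifiers. For 90.9% of genes the positions in the files were identical with it, and coordinates are printed as the files give them (1-based). Totals ran from 30474586 to 35215640 counts per library. Every pair of libraries within a group differed by more than sampling noise over genes, so none was counted as a copy. Values per library are CPM, counts as a share of the library's scaled total, with TMM factors, with the mean ± SD of 4 libraries. Without the strand setting, reads of overlapping genes cannot be told apart.

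Genes were kept by filterByExpr on the groups, which left 16126 of 32927 genes with any count. The test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with TMM scaling and treatment as the only term, two-sided, with Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.222. A count by size added an absolute log2 fold change of at least 1. TMM left the median log2 fold change over all genes at 0.01, and library totals alone at 0.04. There were 44 gene lists, 34 of pathways and 10 of cell types, and 43 of them had at least 3 tested members. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over the lists, with an estimated correlation and fry beside it. Counts of members that rose or fell are over all genes tested, and again adjusted over the list alone.

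The genes named were chosen by a rule. It took the 8 largest rises and 8 largest falls with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups, leaving out predicted genes and pseudogenes by symbol. It added up to 4 members with the smallest p from each list. It always included Hmgcs1, Mki67, Ccnd1, Cdkn1a, Tnnt2, Myh6, Myh7, Nppa, Nppb, Rhob, Klf2, Ccn1 and Ccn2. Some genes the rule took are not reported here and were left out of the search for values that stood apart and of the totals of named genes, but they stay in the counts and tests of lists. The design, this rule, the lists and most alternatives were fixed before the data were examined. Predicted genes named in the closing section, and the genes of symbol families, were chosen after their values were seen.

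The edgeR step and the list tests were tested on simulated data: counts for the 16126 genes were drawn from the means and library sizes of this comparison, with 200 genes changed. The test recovered 20.9% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 100% of those changed 4-fold. Of 129 calls 11 were false, or 8.5%, above the 5% aimed for. Of 100 random lists 0 had a camera p under 0.05. Genes were drawn independently of each other, so the random lists could not test the preset correlation of 0.01. The shares recovered hold for 200 changed genes. The data gave 2805 calls, and the adjusted threshold is less strict where more genes change. The shares therefore do not carry over to this comparison, where smaller changes may still have been missed.

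Alternatives were DESeq2's size factors, library totals alone, the Wald test of DESeq2 1.42.0, limma-voom, no filter beyond 1 count in total, a filter of 1 CPM in at least 4 samples, the replicate number as a block, each library left out in turn, mitochondrial and haemoglobin genes left out, and all libraries thinned to 30474586 counts. Set as a term and each set alone were added after seeing the data. Treatment effects were compared between sets with an interaction term in edgeR, and camera was run on that term for the lists, a test chosen after the results were seen. All 35 splits of the 8 libraries into 4 and 4 were refitted. Library measures were compared with exact permutation tests in Python 3.11.15 (scipy 1.17.1), adjusted over 8 measures. Families of genes with the same symbol stem and at least 8 tested protein-coding members were tested for an excess of changed genes with Fisher's exact test.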

Results

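RNA was sequenced from cultured mouse heart muscle cells, taken from C57/Bl6 hearts at embryonic day 12.5 and grown in control medium or in medium with 10 µM simvastatin. Simvastatin blocks the synthesis of mevalonate, from which cells build sterols and the isoprenoid lipids attached to small GTPases. There were 4 control and 4 simvastatin libraries, each a table of gene counts for 49315 Ensembl genes. Their totals ran from 31457872 to 35215640 counts in the controls and from 30474586 to 34993255 with simvastatin. The comparison asks how blocking the mevalonate pathway changes gene expression in these cells, with proliferation as the study's stated interest. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The file headers name a set for each library: replicates 1 and 3 of each group belong to set 1, replicates 2 and 4 to set 2. What a set was is not given in the sources used here, so values within each set stand beside many of the pooled ones.

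With simvastatin, genes of the cell division cycle and targets of YAP/TEAD and SRF fell, and genes of sterol and fatty acid synthesis rose. Of these lists only those of the cell cycle also passed the list test with an estimated correlation (adjusted p = 0.0267 for each, against adjusted p from 0.09 to 0.402 for the others). With fry, which asks only whether a list's own genes changed, each of these lists passed (fry adjusted p from 6.7e-05 to 0.0236). Of 16126 genes tested, 1256 rose and 1549 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 471 rose and 804 fell at least 2-fold. Set 1 alone gave 1627 changed genes and set 2 alone 2975. The first principal component held 47.0% of the variance and separated the groups, with controls between -46.8 and -33.1 and simvastatin libraries between 30.0 and 52.7.

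Genes of DNA replication and mitosis fell together. Of 32 genes of G2/M and mitosis, 31 fell and 0 rose, with a median log2 fold change of -1.73 (-1.98 in set 1, -1.47 in set 2). The count adjusted over the list alone was also 31. Mki67, the proliferation marker Ki-67 (chromosome 7, 135689784 to 135716361), dropped from 55.1 ± 7.39 to 16.0 ± 1.93 CPM (SD, n = 4 per group), a log2 fold change of -1.78 ± 0.14 (SE, edgeR adjusted p = 3.08e-05). Cdk1, the kinase that drives entry into mitosis (chromosome 10, 69336635 to 69352938), dropped from 124 ± 18.3 to 31.1 ± 3.03 CPM. The mitotic kinase Aurka fell with a log2 fold change of -2.02 and Birc5, which encodes survivin, with -1.74. Of 30 genes of the G1/S transition and replication, 25 fell and 0 rose, with a median of -1.73 (-1.98 in set 1, -1.42 in set 2), and 26 fell adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase (chromosome 12, 24708241 to 24714146), went from 359 ± 28.2 to 63.1 ± 16.3 CPM. Among the subunits of the replicative helicase, Mcm5 had a log2 fold change of -2.19, Mcm3 -2.12 and Mcm7 -1.77. Mcm7 overlaps Ap4m1 and Cops6, and the strand setting of the counting is not given in the sources used here. Cyclin D1 was an exception: Ccnd1 stood at 31.3 ± 13.1 CPM in controls and 25.4 ± 5.64 with simvastatin, a difference within the replicate spread (log2 fold change -0.30, edgeR adjusted p = 0.506). Both lists passed camera, a test of a list against all other genes, with adjusted p of 1.52e-65 for G2/M and 6.98e-48 for G1/S. Both also passed with an estimated correlation (adjusted p = 0.0267 for each).

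Among inhibitors of cyclin-dependent kinases and p53 targets, members moved both ways: 4 of 19 rose and 3 fell (5 and 3 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.366). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 266 ± 6.62 to 424 ± 7.66 CPM. The pro-apoptotic genes Bbc3 and Pmaip1 rose with log2 fold changes of 1.43 and 1.02. Gtse1, which is expressed in G2, fell with -1.54. List medians were 0.02 in set 1 and 0.09 in set 2.

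**Figure D1:**
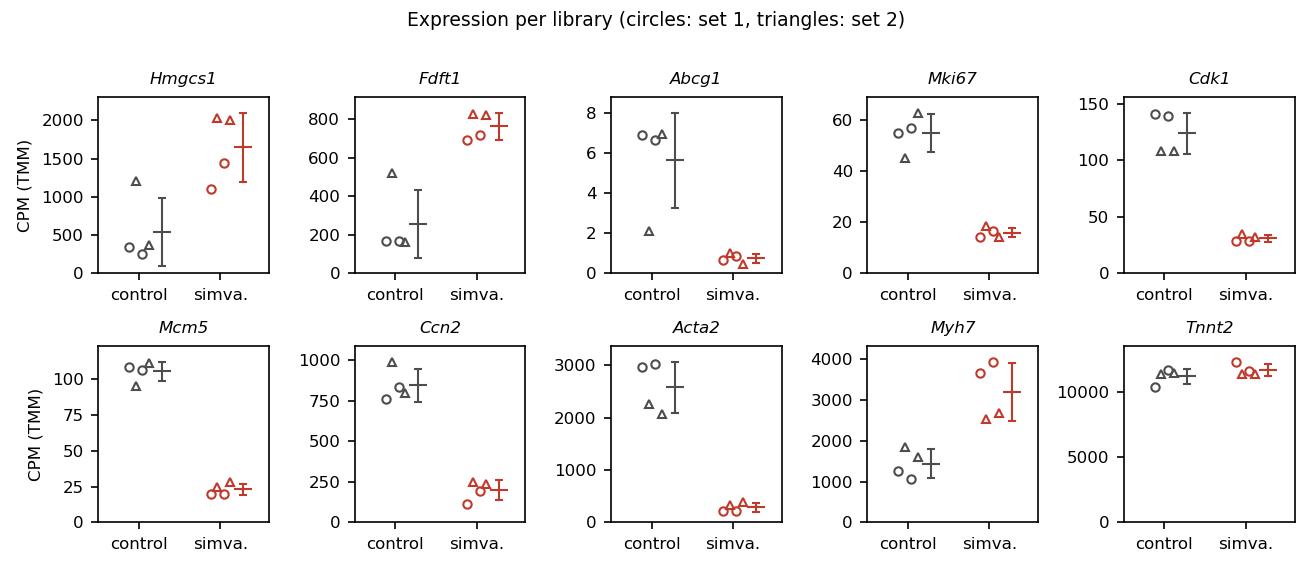
Expression of 10 named genes in each library, in CPM after TMM scaling, on linear axes from 0; points are single libraries (circles set 1, triangles set 2), and dashes with bars are the mean and SD of 4 libraries. Mki67 fell from 55.1 to 16.0 CPM, and for Hmgcs1 control replicate 2 lies at 1203 CPM, away from the other controls at 257 to 377.

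Genes of the mevalonate pathway and of sterol synthesis rose. Of 9 mevalonate and isoprenoid enzymes, 7 rose and 0 fell, with a median log2 fold change of 1.28 (1.53 in set 1, 1.0 in set 2), and 8 rose adjusted over the list alone. Mvk, mevalonate kinase, rose with a log2 fold change of 1.38, Mvd with 1.19 and Pmvk with 0.76. Hmgcs1, which makes HMG-CoA (chromosome 13, 119690462 to 119708086), went from 545 ± 442 to 1648 ± 452 CPM (SD, n = 4 per group; edgeR adjusted p = 0.0314, DESeq2 adjusted p = 0.0528). Of 13 genes of the sterol branch, from squalene synthase to cholesterol, 10 rose and 0 fell, with a median of 1.11 (1.36 in set 1, 0.95 in set 2), and all 13 rose adjusted over the list alone. Tm7sf2 had a log2 fold change of 1.87, Fdft1, which encodes squalene synthase, 1.58 and Ebp 0.89. The lists passed camera with adjusted p of 5.07e-05 and 5.06e-08 but not with an estimated correlation (adjusted p = 0.402 for each).

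The number of calls in these lists depended on which libraries were kept, and control replicate 2 stood apart from the other controls. In that library Hmgcs1 stood at 1203 CPM against 257 to 377 in the other controls, and Fdft1 at 524 against 162 to 171. Without control replicate 2, 8 of 9 mevalonate and 13 of 13 sterol genes rose, with medians of 1.73 and 1.66. With that library kept and any of control replicates 1, 3 or 4 or simvastatin replicates 2, 3 or 4 left out, 3 mevalonate and 6 sterol genes rose, with medians of 1.08 to 1.32 and of 0.98 to 1.17. Those same omissions each ended the calls of Hmgcs1 and Mvd, with adjusted p of up to 0.0834 and 0.0754, and without simvastatin replicate 1 the counts were 6 and 10. Set 2 alone, which holds control replicate 2, gave 2 and 3, and set 1 alone gave 8 and 11.

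Of 12 fatty acid synthesis genes, 7 rose and 0 fell (8 adjusted over the list alone), with a median log2 fold change of 0.82 (0.90 in set 1, 0.72 in set 2). Acss2, which makes acetyl-CoA from acetate, had a log2 fold change of 1.48, Fasn, fatty acid synthase, 1.12, Me1, malic enzyme, 0.84 and Elovl6, a fatty acid elongase, 0.82. That list passed camera with adjusted p of 1.53e-05, against adjusted p = 0.402 with an estimated correlation, and its count ranged from 4 without control replicate 4 to 10 without control replicate 2. Of 12 genes of sterol uptake and feedback, 3 rose and 1 fell (7 and 1 adjusted over the list alone), with medians of 0.41 pooled, 0.52 in set 1 and 0.26 in set 2. Camera's adjusted p was 0.0175, or adjusted p = 0.515 with an estimated correlation. Npc2 rose with a log2 fold change of 0.42 and Tmem97 fell with -0.54. Without control replicate 2, 6 of these genes rose and 0 fell, with 0.50 as the median, and 0 also fell without simvastatin replicate 3. Targets of the oxysterol receptor LXR split: of 9, Abcg1 and Abca1, which export cholesterol, fell with -2.87 and -2.15, and Pltp rose with 1.70. The LXR counts were 3 and 3 adjusted over the list alone, the medians were 0.30 in set 1 and 0.03 in set 2, and camera gave an adjusted p of 0.96. Abcg1 was at 2.10 CPM in control replicate 2 against 6.64 to 6.96 in the other controls.

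Of 15 genes of dolichol and ubiquinone synthesis, 1 rose and 2 fell, the same counts as adjusted over the list alone, with medians of 0.01 in set 1 and -0.09 in set 2 (camera adjusted p = 0.797). Dhdds, a dolichol synthesis enzyme, rose with a log2 fold change of 0.46 and Pdss1 fell with -0.48, and the count of 2 was 1 without control replicate 2, 3 or 4 or simvastatin replicate 1 or 2, and 0 without simvastatin replicate 3. Of 10 enzymes of protein prenylation 0 passed in edgeR, also adjusted over the list alone, 0 in DESeq2 and 0 in limma-voom, and 0 had an unadjusted p under 0.05 in edgeR. In set 1 alone 0 passed, and in set 2 alone 1 rose and 1 fell. Camera gave that list an adjusted p of 0.81. Of the small GTPases and their inhibitors, which carry or bind isoprenoid lipids, 6 of 24 rose and 4 fell (9 and 4 adjusted over the list alone), with medians of 0.20 in set 1 and 0.31 in set 2 (camera adjusted p = 0.0762, adjusted p = 0.654 with an estimated correlation, or adjusted p = 0.0466 with set as a term at the preset correlation). Rhob (chromosome 12, 8497763 to 8499985) went from 4.33 ± 1.58 to 16.8 ± 7.73 CPM and Rhoa from 294 ± 19.5 to 599 ± 77.9 CPM. Rhoa overlaps Tcta, so its value is uncertain without the strand setting. Nras rose with a log2 fold change of 0.51. Rnd3 and Rnd1, which oppose RhoA signalling, fell with -1.39 and -1.35.

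Targets of YAP/TEAD, the transcription factors of the Hippo pathway, fell. Of 21 tested, 15 fell and 1 rose (16 and 1 adjusted over the list alone; 0 rose without simvastatin replicate 3), with a median log2 fold change of -0.84 (-1.05 in set 1, -0.73 in set 2). Ccn2, connective tissue growth factor (chromosome 10, 24595442 to 24598683), dropped from 846 ± 102 to 199 ± 62.8 CPM (SD, n = 4 per group; edgeR adjusted p = 0.000151). Ccn1 fell from 390 ± 75.2 to 81.6 ± 31.6 CPM and Ankrd1, a cardiac stress protein (chromosome 19, 36111965 to 36119844), from 4095 ± 32.7 to 1704 ± 127 CPM. Amotl2 had a log2 fold change of -1.69 and F3, tissue factor, -1.40. Of 24 targets of SRF and genes of the actin cytoskeleton, 17 fell and 1 rose (19 and 2 adjusted over the list alone), with a median of -0.84 (-1.01 in set 1, -0.65 in set 2). Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255336), dropped from 2582 ± 488 to 291 ± 87.0 CPM and Tagln from 159 ± 43.8 to 16.2 ± 6.35 CPM. Actg2 had a log2 fold change of -4.40 and Fhl1 -1.31. Actin genes share sequence and Tagln overlaps Pcsk7, so reads could be divided differently among them. Camera gave adjusted p of 5.34e-12 for YAP/TEAD and 6.63e-15 for SRF targets, against adjusted p = 0.09 and adjusted p = 0.229 with an estimated correlation.

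**Figure D2:**
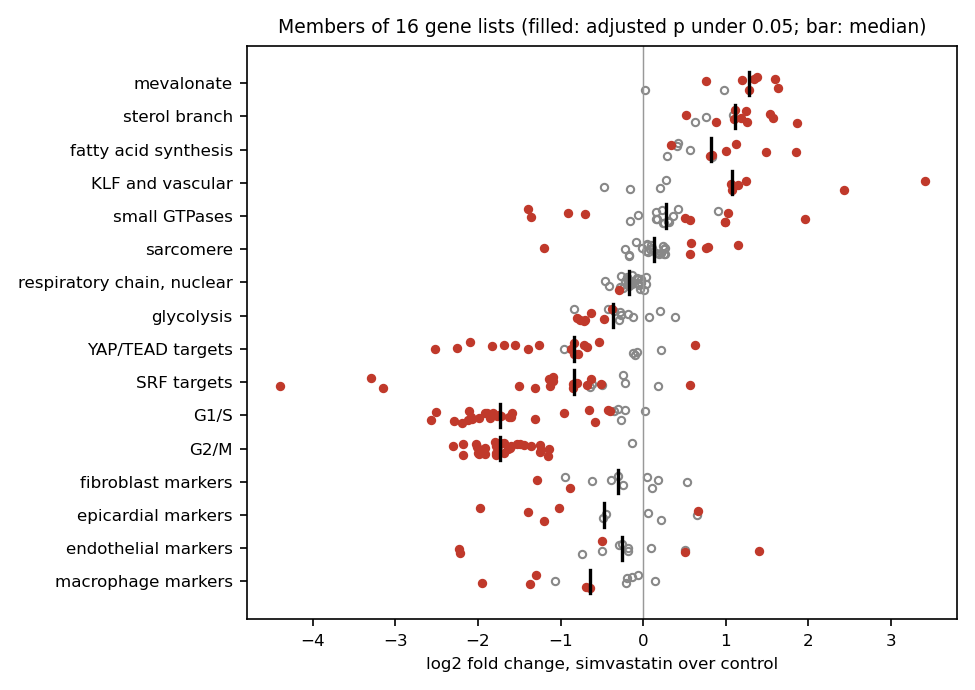
Log2 fold change (simvastatin over control, 4 libraries per group) of each tested member of 16 gene lists; a point is a gene, filled where its edgeR adjusted p is under 0.05, and the bar is the list's median. The G1/S and G2/M medians lie at -1.73 and those of the mevalonate and sterol lists at 1.28 and 1.11.

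The genes with the largest rises were mostly low in control cells. Pi16, a peptidase inhibitor (chromosome 17, 29318877 to 29329413), went from 0.225 ± 0.0737 to 11.0 ± 5.77 CPM (log2 fold change 5.60 ± 0.47, edgeR adjusted p = 4.29e-05). Slc26a10 (chromosome 10, 127172426 to 127180645) went from 0.624 ± 0.231 to 23.3 ± 16.6 CPM. Hdc, the enzyme that makes histamine (chromosome 2, 126593667 to 126619299), rose from 2.54 ± 0.378 to 71.4 ± 18.6 CPM. Serpinb1a, a protease inhibitor (chromosome 13, 32842092 to 32851185), rose from 17.1 ± 3.39 to 248 ± 81.1 CPM. The small nuclear RNA gene Rn7sk had a log2 fold change of 3.64, Lrrn4cl 3.51 and Cdsn 3.27. Klf2, a transcription factor (chromosome 8, 72319033 to 72321656), went from 0.982 ± 0.703 to 10.5 ± 4.49 CPM. Of a list of 10 KLF and vascular genes fixed beforehand, 6 rose and 0 fell, also adjusted over the list alone, with a median of 1.07 (1.09 in set 1, 0.66 in set 2). In that list Klf4 had a log2 fold change of 2.44, Klf3 1.25 and Klf6 1.06. Camera gave an adjusted p of 2.29e-05 for it, against adjusted p = 0.321 with an estimated correlation.

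Among the largest falls outside the actin genes were those of Mogat2, Cxcl5, Ifi47 and Edn1. Mogat2, an acyltransferase of triglyceride synthesis (chromosome 7, 99219084 to 99238619), went from 15.2 ± 5.09 to 0.938 ± 0.594 CPM (log2 fold change -4.01 ± 0.43, edgeR adjusted p = 0.000158). The interferon-inducible GTPase gene Ifi47 had a log2 fold change of -3.33 and overlaps Olfr56. Edn1, which encodes endothelin 1, had -2.93. The chemokine gene Cxcl5 had -3.49 (edgeR adjusted p = 0.0144), but its controls ranged from 2.04 to 25.8 CPM, and limma-voom gave an adjusted p of 0.073. Its log2 fold change was -5.31 in set 1 and -0.78 in set 2.

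Genes of the contractile apparatus moved in both directions, mostly little. Of 26 sarcomere genes 5 rose and 1 fell, also adjusted over the list alone, with a median log2 fold change of 0.13 (0.18 in set 1, 0.11 in set 2). Myh7, the slow myosin heavy chain (chromosome 14, 54970688 to 54994634), went from 1441 ± 347 to 3199 ± 706 CPM (log2 fold change 1.15, edgeR adjusted p = 0.00255). It overlaps the antisense gene Mhrt. Myl2 rose from 2213 ± 278 to 3757 ± 226 CPM, and skeletal actin, Acta1, fell from 395 ± 50.3 to 171 ± 25.4 CPM. Tnnt2, cardiac troponin T, stood at 11193 ± 577 and 11676 ± 443 CPM (log2 fold change 0.06, edgeR adjusted p = 0.699). Myh6 stood at 18628 ± 4434 and 19026 ± 3286 CPM (log2 fold change 0.03, edgeR adjusted p = 0.94). The list passed camera with an adjusted p of 0.0396, against adjusted p = 0.515 with an estimated correlation, and did not pass without control replicate 1 or 3 or simvastatin replicate 2 or 4 (adjusted p 0.067 to 0.0898).

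Of 18 cardiac transcription factor and natriuretic peptide genes 2 rose and 2 fell, also adjusted over the list alone, with 1 and 1 in set 1 alone and 3 and 4 in set 2 alone, and camera gave an adjusted p of 0.826. The natriuretic peptide genes fell: Nppb (chromosome 4, 147985788 to 147987205) from 239 ± 35.1 to 92.6 ± 11.5 CPM, and Nppa from 8139 ± 785 to 5469 ± 516 CPM. Hey2 and Gata6 rose with log2 fold changes of 1.0 and 0.67. Among 21 genes of calcium handling, ion channels and gap junctions 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.346). Gja5, a gap junction gene, had a log2 fold change of 0.62, Cacna1h, a calcium channel, 1.03, and Atp2a2, the sarcoplasmic calcium pump, -0.49. The 2 falls in that list were 1 without control replicate 1, 2 or 4 or simvastatin replicate 1, and 0 without simvastatin replicate 3. Of 8 ventricular markers 3 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0124, or adjusted p = 0.363 with an estimated correlation), and of 11 atrial markers 1 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.35), with 2 rising without control replicate 2. The 3 ventricular markers that rose, Myh7, Myl2 and Hey2, also stand in the sarcomere or cardiac transcription factor lists.

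Of 18 glycolysis genes 7 fell and 0 rose (12 adjusted over the list alone), with a median log2 fold change of -0.37 (-0.44 in set 1, -0.30 in set 2). Eno1, enolase, went from 3092 ± 397 to 1782 ± 139 CPM (log2 fold change -0.80, edgeR adjusted p = 0.000716). Pfkl had -0.76, Hk2 -0.71 and the lactate transporter gene Slc16a3 -0.71. Camera gave an adjusted p of 0.000302, against adjusted p = 0.402 with an estimated correlation. Of 29 nuclear genes of oxidative phosphorylation, Sdhd alone fell (log2 fold change -0.29, edgeR adjusted p = 0.0374), a call that ended in 7 of the 8 fits without a library, while 3 genes fell without control replicate 1. In that list 0 passed adjusted over the list alone, while 5 had an unadjusted p under 0.05 in edgeR, and DESeq2 and limma-voom each called 1. Of 13 mitochondrially encoded genes 0 passed on either count in edgeR, 0 in DESeq2 and 0 in limma-voom, and 0 had an unadjusted p under 0.05 in edgeR. In set 2 alone 2 of these rose and 3 of the nuclear genes fell, and in set 1 alone 0 of either passed. Of 21 genes of fatty acid uptake and oxidation 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.366), among them Ucp2 with 0.84 and Acadvl with -0.42. The 3 rises were 1 without simvastatin replicate 3, and the 2 falls were 1 in every fit without a library except those without control replicate 2 or 4.

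Markers of other heart cell types were present and also moved. Of 9 smooth muscle and pericyte markers 5 fell and 1 rose (6 and 1 adjusted over the list alone), and 3 of these, Acta2, Tagln and Cnn1, also stand in the SRF list. Cspg4 rose with a log2 fold change of 1.06. Camera gave an adjusted p of 6.89e-05, or adjusted p = 0.0706 with an estimated correlation. Of 11 macrophage markers 5 fell and 0 rose, also adjusted over the list alone (median -0.64, camera adjusted p = 0.0124, or adjusted p = 0.402 with an estimated correlation). Cd68 fell from 18.5 ± 0.649 to 11.8 ± 0.868 CPM. Of 10 epicardial markers 4 fell and 1 rose, also adjusted over the list alone: Wt1 fell with -1.98 and Msln rose with 0.67 (camera adjusted p = 0.115, and adjusted p = 0.000616 in set 1 alone). The 4 falls were 2 without control replicate 1 or 3 or simvastatin replicate 1 or 3. Endothelial and endocardial markers split, with 3 of 13 lower and 2 higher (5 and 3 adjusted over the list alone; camera adjusted p = 0.0794). Emcn fell with -2.22 and Npr3 with -2.22, and Tek rose with 1.40, and the 2 rises were 1 in every fit without a library except those without simvastatin replicate 1 or 4.

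Of 11 fibroblast markers, Col3a1 and Pdgfra fell, also adjusted over the list alone, and camera gave an adjusted p of 0.366. The 2 falls were 1 without simvastatin replicate 2 or 3 and 0 without control replicate 1 or 3 or simvastatin replicate 1. In set 1 alone 5 fell and 0 rose (camera adjusted p = 8.06e-05), in set 2 alone 2 fell and 3 rose (camera adjusted p = 0.233), and the list's median was -0.80 in set 1 and 0.28 in set 2. Camera on the interaction of set and treatment passed this list (adjusted p = 6.18e-13, or adjusted p = 0.075 with an estimated correlation) and those of SRF targets, G2/M, NF-kappaB, epicardial markers, G1/S, matrix, YAP/TEAD, smooth muscle, ventricular and TGF-beta genes (adjusted p 5.65e-11 to 0.0351), and none of these passed with an estimated correlation (adjusted p from 0.272 to 0.431 for the others). Col3a1, a collagen of fibroblasts, went from 427 ± 162 to 231 ± 50.8 CPM (edgeR adjusted p = 0.0376), but its log2 fold change was -1.61 in set 1 and -0.07 in set 2. With set as a term its adjusted p was 0.0555 and that of Pdgfra 0.0507. Haemoglobin genes were at trace levels, 0.00118% ± 0.000287 of counts in controls and 0.00278% ± 0.00123 with simvastatin (exact permutation test, two-sided, p = 0.0286, n = 4 per group). Of 6 erythroid markers 3 rose and 0 fell (5 adjusted over the list alone), with camera at an adjusted p of 0.00413, or adjusted p = 0.402 with an estimated correlation. Hbb-y went from 2.92 ± 0.702 to 9.94 ± 4.02 CPM, and 1 of these markers rose without control replicate 3. Of 4 neural markers, Tubb3 alone rose (0.98; 2 adjusted over the list alone; camera adjusted p = 0.0762), and 2 rose without control replicate 1. Of the liver markers only Apoa2 was tested (0.38, edgeR adjusted p = 0.304).

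More genes were detected in the control libraries, 24655 ± 529 against 22789 ± 257 genes with at least 1 count (exact permutation test, two-sided, p = 0.0286, the smallest the design allows, adjusted p = 0.0458 over 8 library measures, n = 4 per group). The share of mitochondrial counts was 1.99% ± 0.374 in controls and 1.98% ± 0.217 with simvastatin (exact permutation p = 0.971, n = 4 per group).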

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

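The tests of control replicate 2, of read density on silent genes, of other cell types and of the sets were chosen after the results were seen. The splits of the libraries were planned. The test on summed receptor genes was written before its own result, but for satellite-like genes whose values had been seen. Values that stood apart were found with Dixon's 95% rule, which compares a library's gap to its nearest neighbour with the range of its group of 4, and which picks about 1 in 20 groups by chance. Of 366 groups 16 (4.4%) held such a value. Of these 16, 7 were in control replicate 2, 1 in control replicate 1, 1 in control replicate 3 and 0 in control replicate 4, and 3, 3, 1 and 0 in simvastatin replicates 1 to 4.

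In control replicate 2, Hmgcs1 was at 1203 CPM (other controls 257 to 377), Fdft1 at 524 (162 to 171), Mvd at 184 (60.3 to 70.6), Me1 at 47.9 (33.4 to 35.8) and Tm7sf2 at 30.5 (9.60 to 11.4). Abcg1 was at 2.10 (6.64 to 6.96) and Acta1 at 469 (360 to 377).

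Over the 17 sterol and mevalonate genes that rose, control replicate 2 lay a median share of 0.66 of the way from the other controls to the simvastatin mean. RNA of simvastatin-treated cells in this library, by mixing or a wrong label, could account for that only if other raised genes lay at a like share. The 24 genes outside the lipid lists that rose at least 4-fold had a median share of -0.00087 (quartiles -0.043 and 0.041), which argues against it. A difference between the sets would also move control replicate 4, of the same set, but against control replicates 1 and 3 its median share was -0.01, with 0.67 for control replicate 2. What set this library apart stays open, and no biological explanation was tested, since the labels name no difference among the controls.

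The control libraries held more reads in silent and repeat-like genes: the satellite-like predicted genes Gm26870, Gm10800, Gm10801 and Gm21738 fell 31.7-fold, 25.7-fold, 20.6-fold and 21.1-fold with simvastatin, and more genes were detected in controls. The satellite-like genes' summed CPM was 39.1 in control replicate 1, 185 to 373 in the other controls and 2.66 to 17.6 with simvastatin, and 102 receptor genes had a count in control replicate 1 against 258 to 299 in the other controls.

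Genomic DNA in the control libraries is a candidate explanation for the satellite-like genes and the genes detected, and it would raise olfactory and vomeronasal receptor genes as well. The receptor genes' summed CPM was higher in every control (10.6 to 17.8) than in every simvastatin library (5.51 to 6.25), but its log2 fold change of -1.39 (-1.53 to -1.31 with each library left out) lay between the bounds of -2 and -0.58 set beforehand. That sum also held receptor genes with more than 10 counts in a library. Olfactory receptors with at most 10 held 1307 counts in controls and 306 with simvastatin over 3569.8 kilobases. Their relative densities per kilobase, scaled by library totals, were 2.69 and 0.676. Such vomeronasal receptors held 251 and 89 counts over 741.5 kilobases, with relative densities of 2.49 and 0.946. These densities serve for comparison only and are not CPM, and no bound was set for them. The excess per kilobase on vomeronasal receptors was 0.765 times that on olfactory receptors (95% counting interval 0.596 to 0.983), where even cover would give 1, and this also lay between the bounds set for it. Genomic DNA thus cannot be told apart from an effect of simvastatin on these genes, because both tests fell between their bounds; at the measured density 0 of the 1545 other genes that fell would owe over 10% of their fall to it, an estimate that cannot be made for repeat-like genes, whose copy number was not measured.

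The fall of cell cycle, YAP/TEAD and SRF genes could come from fewer non-myocytes in the simvastatin libraries, and then fibroblast, epicardial, endothelial and macrophage markers would fall alike. The 45 markers tested, of which Col1a1 at 796 ± 358 CPM was the most abundant in controls, had a median log2 fold change of -0.30 (SD 0.79), with 13 higher and 32 lower, or -0.55 (SD 1.04) in set 1 and -0.20 (SD 0.79) in set 2; smooth muscle and pericyte markers, 3 of which are in the SRF list, were not among them, and with these the 54 had -0.42 (SD 0.96). Each of these lies above the G2/M median for the same libraries (-1.73, or -1.98 in set 1 and -1.47 in set 2) by more than its SD. The SD is the spread of the markers, not an error of a cell share. This argues against an even loss of these cell types as the whole cause of the fall of cell cycle genes. Loss of only some of their cells was not tested. For the YAP/TEAD and SRF lists, fewer non-myocytes cannot be told apart, since -0.30 lies within its SD of their medians of -0.84. By design the sets cannot be the source of these falls, since both groups held libraries of both sets in equal number. The smallest of these lists' falls in either set was -0.65. The falls were smaller in set 2 by camera on the interaction (adjusted p 5.65e-11 for SRF, 6.99e-07 for G2/M, 9.61e-06 for G1/S and 0.000139 for YAP/TEAD, or adjusted p = 0.272 to 0.431 with an estimated correlation). An effect of simvastatin on cell cycle genes within the cells is a hypothesis that stays open.

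All 35 splits of the 8 libraries into 4 and 4 were refitted. Only 1, the real split, gave as many changed genes as 2805, and only 1 as many as 1275 at 2-fold or more. That is the smallest share that 35 splits can give. Every other split mixed control and simvastatin libraries, which widens the spread within its groups and lowers its counts. The splits therefore do not exclude chance for either count. Of the 35 splits, 18 keep the sets balanced, as the real split does. Of the 18 only 1, the real split, gave as many of either, but 18 are too few for a share under 0.05. The highest of the other splits gave 0 in edgeR for each, with 75 to 1591 genes at an unadjusted p under 0.05, and no other tool was run on the splits. For the number of lists, 5 of 35 splits gave at least the 17 of the real split, and the highest other gave 21. With the sets balanced it was 3 of the 18, with 20 as the highest other. Each other split with at least 17 lists put 3 controls and 1 simvastatin library together, so it still held part of the treatment difference. The splits therefore cannot decide whether chance gave the number of lists. The split by set gave 13 lists and 0 genes in edgeR, with 1591 at an unadjusted p under 0.05.

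The log2 fold change with simvastatin differed between the sets for 9 genes by an interaction term in edgeR, with adjusted p from 0.0277 to 0.0449 and 1850 genes at an unadjusted p under 0.05. For each of the 9, the controls of set 1 lay above those of set 2, and the simvastatin libraries of set 1 below those of set 2. The term therefore also holds a difference between the controls. Set 2 minus set 1, the log2 fold change differed by 1.52 for Col3a1, 2.16 for Col8a1, 2.02 for Ccl7, 1.38 for Col1a2, 1.55 for Anxa1, 2.44 for Tcf21, 2.04 for Ccl2, 1.21 for Acta2 and 2.94 for Steap4. Col1a2 was at -0.90 in set 1 and 0.50 in set 2, Steap4 at -2.43 and 0.53, Acta2 at -3.80 and -2.57, and Col8a1 at -3.95 and -1.77. In controls Col1a2 was at 598 and 561 CPM in set 1 against 272 and 237 in set 2. With simvastatin it was at 308 and 321 against 338 and 383. Col8a1 differed more with simvastatin, at 13.9 and 14.7 CPM in set 1 against 50.3 and 40.1 in set 2. Col8a1, Anxa1 and Steap4 stand in none of the lists and were named after their values were seen.

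The other values that stood apart follow. Cdsn was at 2.95 CPM in control replicate 3 (others 1.04 to 1.1). Sephs2 was at 20.7 in control replicate 1 (68.0 to 71.5). In simvastatin replicate 1, Rnd3 was at 34.8 (54.6 to 57.9), Gata6 at 34.8 (27.9 to 28.6) and Adgre1 at 11.7 (16.8 to 17.3). In simvastatin replicate 2, Mvk was at 126 (117 to 118) and Acadvl at 288 (268 to 269), and its total of 35.0 M counts compared with 30.5 to 30.9 M. Chml was at 10.7 in simvastatin replicate 3 (7.47 to 7.83).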

How the results depend on the processing

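Set as a term and each set alone were chosen after seeing the data, and the other alternatives were planned. The count of 2805 changed genes ranged from 2653 with the CPM filter to 3436 with DESeq2's Wald test over the planned settings that kept all libraries and used no block. It ranged from 2002 without simvastatin replicate 3 to 2462 without control replicate 2, and was 3362 with set as a term, 2975 in set 2 alone and 1627 in set 1 alone, for which the cause was not tested. With a library left out, 1140 to 1314 genes changed at least 2-fold and 17 to 19 lists passed. Camera with an estimated correlation passed 2 lists against 17 at the preset 0.01, the cause of which was not tested beyond that construction. Fry, which asks a different question, passed 21 lists. These were the 17 and the lists of CDK inhibitors and p53 targets (fry adjusted p = 0.0154), atrial (0.0331), endothelial (0.0331) and neural markers (0.00374). Depth moved little: thinned to the smallest library, 2779 genes passed.

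Among values of the named genes reported here with a library left out, 1305 kept direction and side of the threshold, 103 lost the call and 12 gained it. At least 1 such omission ended the calls of Adgre1, Adm, Aldh1a2, Atp2a2, Axin2, Bik, Bmf, Cat, Col3a1, Coq7, Eng, Fabp3, Gpx1, Hba-a2, Hbb-bt, Hmgcs1, Hspa1b, Irf7, Kcnh2, Mvd, Pdgfra, Pdss1, Plin2, Sdhd and Tmem97. Bik lost it in 8 of 8. With all libraries kept and no block, calls ended for Hmgcs1 with DESeq2 (adjusted p = 0.0528), for Cxcl5, Bmf, Pdgfra and Col3a1 with limma-voom (0.0507 to 0.073), for Coq7, Sdhd, Fabp3, Cat and Bik with no filter (0.0551 to 0.149), for Hspa1b with library totals (0.0515) and with thinning (0.0505), and for Pdgfra and Col3a1 with set as a term (0.0507 and 0.0555). In camera, hypoxia genes passed without control replicate 4 or simvastatin replicates 1 or 4 (adjusted p 0.026 to 0.0286), NRF2 targets without control replicate 3 or simvastatin replicate 2 (0.0466 and 0.0214), interferon genes without control replicate 2 or simvastatin replicate 3 (0.0362 and 0.0182), small GTPases without control replicate 3 or simvastatin replicate 2 (0.0167 and 0.031), nuclear oxidative phosphorylation genes without control replicate 1 (0.0143), and epicardial markers without control replicate 4 (0.0299) and endothelial markers without simvastatin replicate 3 (0.0469). In set 1 alone the lists of fibroblast markers (8.06e-05), epicardial markers (0.000616), matrix genes (0.0028) and NRF2 targets (0.0452) passed. In set 2 alone small GTPases (0.0307), hypoxia genes (0.0126) and endothelial markers (0.038) passed, and the lists of sterol uptake (0.0843), sarcomere (0.112), NF-kappaB (0.0756), ventricular (0.0576) and macrophage genes (0.195) did not pass.

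The replicate numbers showed no pairing in the data, though a check on 4 libraries per group could miss one. Deviations of same-numbered libraries correlated at -0.14, 0.05, 0.13 and -0.16, and none of the 4 controls correlated best with its own number. With the replicate block, 2131 genes changed, 1153 at least 2-fold, and 19 lists passed, with hypoxia genes (0.0465) and NRF2 targets (0.0431) gained. Among named genes 2 calls were gained and 17 lost: Adm, Aldh1a2, Atp2a2, Axin2, Bik, Bmf, Cat, Col3a1, Coq7, Cxcl5, Fabp3, Gpx1, Hbb-bt, Kcnh2, Pdgfra, Pdss1 and Sdhd. With set as a term, NRF2 targets (0.0298) and small GTPases (0.0466) were gained.

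Results that did not pass and changed direction have causes that were not tested. List adjusted p in the other direction were 0.988 with DESeq2's size factors (unfolded protein response), 0.92 with the replicate block (LXR targets) and 0.943 with fry (Wnt targets). In set 1 alone they were 0.774 (LXR targets) and 0.897 (selenoproteins). In set 2 alone they were 0.709 for prenylation enzymes, heat shock genes and Wnt targets, 0.742 (cardiac transcription factors), 0.966 (unfolded protein response), 0.233 (fibroblast) and 0.802 (epicardial markers). In set 2 alone log2 fold changes were -0.32 for Chml, -0.002 for Lef1, 0.12 for Ccnd1 and -0.075 for Myh6. With a library left out, log2 fold changes ranged from -0.457 to 0.02 (Ccnd1) and -0.092 to 0.166 (Myh6). List adjusted p ranged from 0.5 to 0.995 (LXR targets), 0.675 to 0.979 (cardiac transcription factors), 0.168 to 0.997 (mitochondrially encoded genes), 0.776 to 0.978 (unfolded protein response), 0.511 to 0.997 (selenoproteins) and 0.646 to 0.96 (Wnt targets), with the direction turning in at least 1 omission each.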

Other observations

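The tests of symbol families, the genes named from them and the test for Rn7sk on genes of at least 1 CPM were chosen after the results were seen. The lists were planned, and the first test for Rn7sk was written before its own result was seen. Of 13 TGF-beta genes, which include the ligand genes Tgfb1 and Tgfb3, 3 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00413, or adjusted p = 0.321 with an estimated correlation). Tgfb3, a growth factor of the developing heart, went from 90.6 ± 5.69 to 26.0 ± 3.29 CPM, Ltbp2 had a log2 fold change of -2.23, and Id2 rose with 0.80. Of 13 NF-kappaB and cytokine genes 5 fell and 0 rose (6 adjusted over the list alone; camera adjusted p = 0.0115, or adjusted p = 0.504 with an estimated correlation). The chemokine gene Cxcl12 went from 355 ± 99.7 to 90.3 ± 22.0 CPM and Ptgs2, cyclooxygenase 2, from 29.8 ± 6.54 to 10.8 ± 2.30 CPM. Of 22 matrix genes 6 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.138): Thbs1, thrombospondin 1, had a log2 fold change of -2.29, Mmp2 -1.35, Tnc -0.99 and Hapln1 1.83. Of 12 hypoxia genes 5 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.0762), among them Egln3 with -1.59, Bnip3 with -0.86 and Ndrg1 with 1.20. Of the hypoxia genes 3 fell without control replicate 1 or 2 and 2 without simvastatin replicate 2 or 3, of the TGF-beta genes 5 fell without control replicate 4, and of the matrix genes 2 rose without control replicate 1.

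Of 12 NRF2 targets 4 rose and 0 fell (5 adjusted over the list alone; camera adjusted p = 0.0762, adjusted p = 0.515 with an estimated correlation, or adjusted p = 0.0298 with set as a term at the preset correlation), among them Nqo1 with a log2 fold change of 1.41, Srxn1 with 0.99 and Sqstm1 with 0.58. Of 22 genes of the unfolded protein and integrated stress responses 3 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.992): Slc7a11 had 1.39, Trib3 1.08 and Phgdh, of serine synthesis, -0.76. Of 13 heat shock genes 2 rose and 1 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.705). Of 15 immediate early genes 2 rose and 2 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.631), with Btg2, which restrains proliferation, at 1.01 and Junb at -0.83. Of 12 interferon genes 2 rose and 0 fell (3 adjusted over the list alone; camera adjusted p = 0.117). Of 11 BCL2 family genes 1 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.797), with Bcl2 at -0.74. Of 14 selenoprotein genes 1 fell, and 0 adjusted over the list alone (camera adjusted p = 0.826). Leaving out a library moved several of these small counts. Of heat shock genes 1 rose in every such fit except those without control replicate 1 or 3, and 2 fell without control replicate 3. Of BCL2 family genes 0 rose except without control replicate 3 or simvastatin replicate 1, and 1 fell except without control replicate 1 or simvastatin replicate 1. Of immediate early genes 4 fell without control replicate 4, of interferon genes 1 rose without control replicate 3 or simvastatin replicate 2 or 4, and of selenoprotein genes 0 fell without control replicate 2 or 3 or simvastatin replicate 2, 3 or 4. Few Hedgehog and Wnt targets were tested: of 3, Osr1 fell with -1.47 (2 fell adjusted over the list alone; camera adjusted p = 0.309), and of 7, Axin2 rose with 1.74 (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.992; 0 rose without control replicate 3 or 4 or simvastatin replicate 3).

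Among 234 families of genes that share a symbol stem, 7 family tests passed in Fisher's exact test over 13204 protein-coding genes. Genes fell in 8 of 10 Mcm (adjusted p = 0.000338), 10 of 21 Nup (adjusted p = 0.00599), 6 of 8 Haus (adjusted p = 0.00599), 12 of 34 Kif (adjusted p = 0.0175) and 8 of 18 Rad genes (adjusted p = 0.0294), and rose in 6 of 13 Hspa (adjusted p = 0.0326) and 6 of 14 Klf genes (adjusted p = 0.0454). In the other direction 5 Kif genes rose and 1 Hspa gene fell, with 0 in the other 5 families. Nup genes encode nuclear pore proteins and Haus genes the augmin complex, which adds microtubules to the spindle. Haus8 went from 121 ± 7.16 to 58.6 ± 4.63 CPM and Nup62 from 172 ± 13.0 to 105 ± 6.10 CPM. Klf8 rose with a log2 fold change of 1.55. Genes of a family are not independent, so these p-values describe an excess among genes only.

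Rn7sk, the 7SK RNA that holds back transcription elongation, was at 0.809 to 2.98 CPM in controls and at 35.2, 7.23, 32.4 and 10.8 CPM in simvastatin replicates 1 to 4. As a hypothesis, more carry-over of RNAs without a poly(A) tail could raise it. The other 29 small structural RNA genes tested had a median log2 fold change of 0.12 (-0.03 to 0.16 with each library left out, from ratios of mean CPM). This met the bound of 0.5 set beforehand against carry-over, but 23 of the 29 were below 1 CPM, near the floor, which excludes little. The other 6 had a median of 0.29 (SD 0.29; 0.05 to 0.53 with each library left out), far below the 3.64 of Rn7sk. This argues against an even carry-over of such RNAs as the whole source of the rise, while a small part of it stays open. Among the 6, Rn7s1, Rn7s2 and Rn7s6 share a symbol stem, and Gm23849, Snord104 and Rpph1 had group means of 0.981 to 1.86 CPM. They are therefore fewer than 6 separate checks, and the kind of library is not given. Gm25373, a predicted small nucleolar RNA gene named after its value was seen, rose with 1.22 (edgeR adjusted p = 0.0393). Rn7s1 and Rn7s2, which encode parts of the signal recognition particle, had 0.30 and 0.47 (edgeR adjusted p = 0.483 and 0.373). No other explanation for Rn7sk was tested.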
